A study of Mus musculus with 23 samples.

How the data were processed

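Gene expression was measured by polyA-selected, single-end Illumina RNA sequencing of liver, per the labels' protocols, in 23 mice, each mouse giving 1 library. The deposited files hold raw counts, the number of reads per gene and library, and the authors counted them with featureCounts 1.4.4 against UCSC mm10 gene models, per the file headers. The counting took exons grouped by gene, kept primary alignments, ignored strand and counted a read for every gene it overlapped, per the file headers. Reads had been aligned with STAR 2.4.0 to mm10, which is GRCm38, per the submitters' processing notes. A read over overlapping or antisense genes cannot be given to 1 of them from such counts, and a read that matched several similar genes was counted at its primary alignment, which need not be its origin. Coordinates are those of the deposited files on mm10, and 62 genes are listed there on more than 1 chromosome. The values carry no normalization by the authors.

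Groups were taken from the labels: WT or KO for Ehhadh, with saline or L-AC. Replicates are separate animals, numbered within a group in accession order, so that equal numbers in 2 groups do not pair animals, and no batch or date is given in the labels. The 56 pairs of replicates were checked for a library deposited more than once by a chi-square over genes with at least 20 reads, and the lowest chi-square per degree of freedom was 44.05, far above sampling noise. Ddx3y, which lies on the Y chromosome, had 1668 to 3973 reads in the 23 libraries and Xist at most 58.

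Totals ran from 24521896 to 48095959 counted reads per library, over 24062 genes. Genes were kept by filterByExpr of edgeR by group (minimum count 10, minimum total 15), which left 14196 genes with at least 99.95% of the reads of each library. Counts were scaled by TMM and fitted with 1 mean per group over all 23 libraries by the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit and glmQLFTest). All p-values are two-sided. Adjusted p-values are Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. SE is the standard error of a log2 fold change, its size divided by the square root of the F statistic. CPM, the usual unit of scaled counts, were taken over the TMM-scaled library size. The 5 contrasts were KO against WT under saline, KO against WT under L-AC, L-AC against saline in WT, L-AC against saline in KO, and the interaction of genotype and treatment.

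The 37 gene lists hold 468 symbols of liver pathways and of markers of other cell types, of which 463 matched by their own name, 1 by a synonym and 4 had no match, and 429 were tested. The list of cholesterol synthesis genes was written knowing that the title of the series names cholesterol homeostasis. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the 37 lists within a contrast, and again with the correlation estimated from the residuals. In text, the counts of a list are its members called over all genes unless "adjusted over the list alone" is written. Fisher's exact test compared the share of called genes within 10 Mb of Ehhadh with that elsewhere.

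The groups, contrasts, tests, alternatives and rule for named genes were fixed before the data were examined. The rule took Ehhadh, the 6 rising and 6 falling genes with the largest fold change in each pairwise contrast (called, at a mean of at least 1 CPM and not named as a predicted transcript), and from each list up to 4 called members with the smallest p, or up to 8 for cholesterol synthesis. Where no member was called, the member with the smallest p could be named. Some genes that the rule takes are not reported here. Other genes named, such as those called by another tool, fit or contrast or when adjusted over a list alone, were chosen after their values were seen. The contrast averaged over treatments, the permutation tests of list scores, and the tests of Ehhadh's neighbours at an unadjusted p, within 40 Mb and over whole chromosomes were added after the data were seen.

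The fits were tested on simulated counts with the library sizes and group sizes of the real data, in which 50 genes each were changed 1.5-, 2-, 4- and 8-fold. At 4-fold, 96%, 98%, 98% and 94% of them were recovered in the 4 pairwise contrasts in the order given, and 4.29%, 1.95%, 4.86% and 8.24% of the calls were genes left unchanged. Each simulated gene had 1 mean, taken over all 23 libraries, and genes were drawn independently. The simulation thus held no correlation between genes and no unlabelled structure of the samples, so these shares need not hold for the real comparisons. Alternatives were the size factors of DESeq2 in edgeR, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 1 CPM in 5 libraries, age in weeks as a covariate, a fit of only the groups compared, an adjusted p under 0.01, windows of 5 and 20 Mb around Ehhadh, and each library left out in turn. Exact permutation tests enumerated all splits of the libraries compared. Figures were drawn with matplotlib 3.10.9.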

Results

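Liver RNA was sequenced from 23 mice of a mixed B6/129 background in 4 groups set by genotype and treatment. Ehhadh encodes the peroxisomal L-bifunctional protein, an enzyme of peroxisomal fatty acid beta-oxidation, and wild-type (WT) mice were compared with Ehhadh knockout (KO) mice. Each genotype received saline or L-AC, which the labels give only by that abbreviation. As background, L-aminocarnitine is an inhibitor of carnitine palmitoyltransferase 2 and so of mitochondrial long-chain fatty acid oxidation. There were 7 WT mice on saline (29 to 45 weeks old), 5 KO mice on saline (31 to 44 weeks), 6 WT mice on L-AC (28 to 44 weeks) and 5 KO mice on L-AC (28 to 38 weeks). Each library held 24521896 to 48095959 counted reads. The totals were 30352749 to 47524125 in WT saline, 24656392 to 48095959 in KO saline, 24521896 to 47824552 in WT L-AC and 26325848 to 31206300 in KO L-AC. The median correlation of log2 CPM (counts scaled by library size) between replicates of a group was 0.983, 0.986, 0.984 and 0.977 in the same order. The first principal component held 55.2% of the variance, and it placed the saline libraries between -50.76 and -28.09 and the L-AC libraries between 26.4 and 68.54. WT saline replicate 1 lay nearest to the L-AC libraries on it and highest on the third component (42.67).

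The targeted gene separated the genotypes in all 23 libraries within each treatment. Ehhadh lies on chromosome 16 from 21761285 to 21787834 on the minus strand of mm10. Its level in the WT saline libraries was 910.2, 884.1, 755.2, 1104, 755, 634.8 and 1635 CPM for replicates 1 to 7, a mean of 954 ± 335.1 CPM (SD, n = 7). The KO saline libraries had 131.6, 127.1, 252.9, 105.5 and 90.92 CPM, a mean of 141.6 ± 64.35 CPM (SD, n = 5). Under L-AC the WT libraries had 13730, 13210, 10260, 14170, 12190 and 14650 CPM (mean 13040 ± 1602 SD, n = 6). The KO L-AC libraries had 2144, 1476, 1421, 1631 and 1617 CPM (mean 1658 ± 286.3 SD, n = 5). KO livers held 14.8% of the WT level under saline and 12.7% under L-AC. L-AC raised Ehhadh 13.7-fold in WT (log2 fold change 3.77, SE 0.233, adjusted p = 3.53e-11) and 11.7-fold in KO (3.55, SE 0.269, adjusted p = 1.15e-09). The difference between these responses was -0.22 on the log2 scale (SE 0.324, adjusted p = 1). A count sums the reads over all exons of a gene, and the labels do not say which part of Ehhadh was removed.

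**Figure D1:**
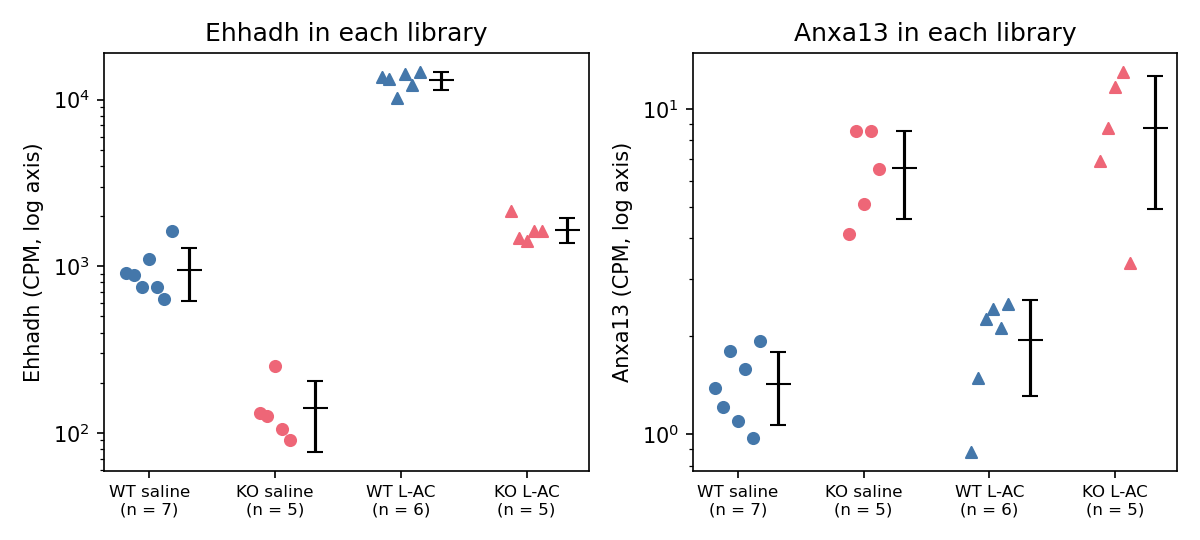
Level in CPM (log axis) of Ehhadh and Anxa13 in each of the 23 libraries, circles for saline and triangles for L-AC, blue for WT and red for KO, with black bars for the group mean ± SD. Ehhadh is lower and Anxa13 higher in every KO library than in every WT library of the same treatment.

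The comparison of KO with WT livers under saline (5 against 7 mice) asked what loss of Ehhadh changed without L-AC. Besides Ehhadh, which was 6.74-fold lower (log2 fold change -2.75, SE 0.251, adjusted p = 1.94e-06), 1 gene passed the test. Anxa13, an annexin that binds membranes in the presence of calcium (chromosome 15, 58341464 to 58389274), was 4.57-fold higher (2.19, SE 0.288, adjusted p = 0.00073). Its level was 1.429 ± 0.3611 CPM in WT and 6.567 ± 1.994 CPM in KO (SD), and each of the 5 KO libraries lay above all 7 WT libraries. At an unadjusted p under 0.05 there were 264 genes, where 710 are expected by chance among the 14196 tested. The count of 2 genes became 9 with DESeq2, 5 without KO saline replicate 1 and 4 without KO L-AC replicate 2. In simulated data of the same size, with 50 genes changed at each fold, the same test recovered 40% of genes changed 1.5-fold and 76% of genes changed 2-fold. Recovery may be lower where few genes change, since the adjustment of p is then stricter.

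Of the 37 gene lists, 4 differed between KO and WT under saline by camera with its preset correlation, and none of the 4 held a member called by edgeR, DESeq2 or limma-voom over all genes or by edgeR when adjusted over the list alone. Genes of cholesterol synthesis were higher in KO, with 19 of 20 members positive and a median log2 fold change of 0.41 (adjusted p = 8.63e-13). With an estimated correlation the adjusted p was 0.77, and 5 members were under 0.05 unadjusted. Endothelial markers were higher by a median of 0.12 (7 of 8 positive, adjusted p = 0.0055), a call lost without WT saline replicates 1 or 2 or KO saline replicates 2 or 3 (adjusted p 0.0941 to 0.154). ER chaperones were lower by a median log2 fold change of -0.24 (2 of 14 positive, adjusted p = 0.00856), a call lost without WT saline replicates 1 or 6 or KO saline replicates 2, 3 or 4 (adjusted p 0.0787 to 0.43). Acute phase genes, which encode secreted plasma proteins of inflammation, had a median of -0.17 (1 of 19 positive, adjusted p = 0.0127), and that call was lost without WT saline replicates 1, 3 or 6 or KO saline replicates 2, 3 or 4 (adjusted p 0.0521 to 0.628). These 3 lists also had an adjusted p of 0.77 with an estimated correlation, and 1, 0 and 0 of their members were under 0.05 unadjusted. Among the lists that did not pass, the 27 tested genes of peroxisomal beta-oxidation other than Ehhadh had a median of 0.01 (adjusted p = 0.701) and the 18 of mitochondrial fatty acid oxidation a median of 0.00 (adjusted p = 0.891).

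Under L-AC the same comparison (5 KO against 6 WT mice) also gave 2 called genes, Ehhadh at 7.86-fold lower (-2.98, SE 0.257, adjusted p = 6.87e-07) and Anxa13 at 4.49-fold higher (2.17, SE 0.298, adjusted p = 0.00159). Anxa13 stood at 1.948 ± 0.6342 CPM in WT and 8.746 ± 3.838 CPM in KO (SD). Its call was lost in a fit of only the groups compared (2.16, adjusted p = 0.0605). Genes at an unadjusted p under 0.05 numbered 643. The count of called genes became 16 with DESeq2, 5 in the fit of only the groups compared, 6 without KO L-AC replicate 4 and 4 without WT L-AC replicate 4 or KO L-AC replicate 2. The simulated data gave a recovery of 44% at 1.5-fold and 56% at 2-fold for this comparison, with the same limit as under saline.

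Cholesterol synthesis genes were higher in KO than in WT livers under L-AC, with 19 of 20 members positive and a median log2 fold change of 0.47 (mean 0.56, adjusted p = 1.9e-12 by camera). The adjusted p was 0.434 with an estimated correlation. No member passed over all genes by edgeR, DESeq2 or limma-voom, 9 were under 0.05 unadjusted, and 6 passed when adjusted over the list alone. Those 6, named after their values were seen, were Idi1 (1.48, SE 0.435), Sqle (1.41, SE 0.473), Msmo1 (1.04, SE 0.387), Fdps (1.02, SE 0.344), Nsdhl (0.85, SE 0.279) and Cyp51 (0.80, SE 0.29), enzymes from isoprenoid formation to the last steps of sterol synthesis. Genes of sterol uptake and SREBP2 feedback were higher by a median of 0.10 (mean 0.34, 6 of 7 positive, adjusted p = 0.00535, and adjusted p = 0.748 with an estimated correlation). Adjusted over the list alone, 3 of them passed, among them Insig1, which holds SREBP in the endoplasmic reticulum (0.62, SE 0.183). This call was lost without KO L-AC replicate 4 (adjusted p = 0.0809). The mean log2 CPM of the 20 cholesterol synthesis genes was 4.516 ± 0.076 in WT L-AC and 5.071 ± 0.163 in KO L-AC (SD), against 5.761 ± 0.575 in WT saline and 6.212 ± 0.546 in KO saline. An exact permutation test of this score, added after the data were seen, gave two-sided p = 0.208 under saline (n = 7 and 5) and p = 0.00216 under L-AC (n = 6 and 5), the smallest its 462 splits can give (adjusted p = 0.0801 over the 37 lists).

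**Figure D2:**
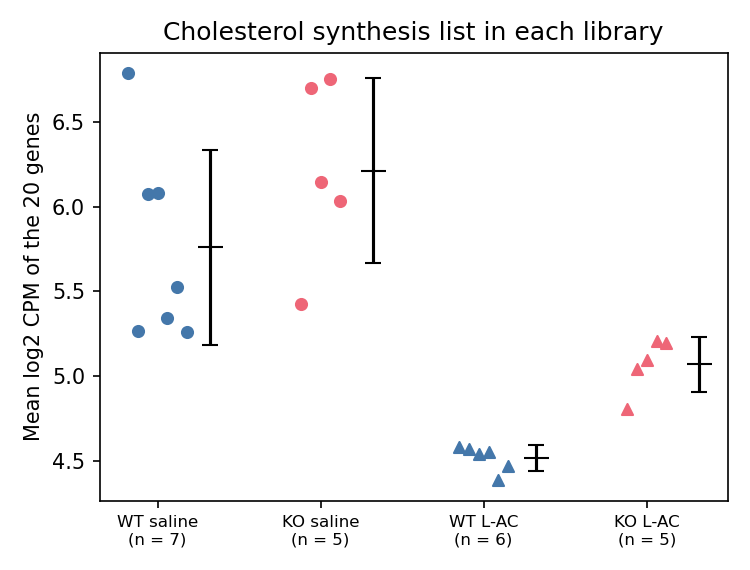
Mean log2 CPM of the 20 cholesterol synthesis genes in each library, circles for saline and triangles for L-AC, blue for WT and red for KO, with black bars for the group mean ± SD. Under L-AC the 5 KO libraries lie between 4.807 and 5.21 and the 6 WT libraries between 4.386 and 4.581, whereas the saline groups overlap.

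Targets of ATF4, the transcription factor of the amino acid response, were higher in KO than in WT livers under L-AC (15 of 18 positive, median 0.62, adjusted p = 3.12e-05). The adjusted p was 0.434 with an estimated correlation, and no member passed over all genes by edgeR, DESeq2 or limma-voom, with 7 under 0.05 unadjusted. Adjusted over the list alone, 2 members passed: Slc7a11, the cystine importer (1.76, SE 0.555), and Ddit3, a transcription factor of the stress response (1.15, SE 0.325). The value of Slc7a11 rests on KO L-AC replicate 3, at 7.733 CPM, while the other KO libraries lay at 0.6077 to 0.6791 CPM, within the 0.3321 to 0.7273 CPM of WT libraries under L-AC. Ddit3 was at 24.22 and 23.2 CPM in KO L-AC replicates 2 and 3 and at 5.773 to 9.653 CPM in the others, against 4.152 to 9.26 CPM in WT. Without KO L-AC replicate 3 the adjusted p of the list was 0.0339. Genes of bile acid synthesis were lower in KO, with 0 of 10 positive and a median of -0.19 (adjusted p = 0.0248, and adjusted p = 0.434 with an estimated correlation). That call was lost without WT L-AC replicates 1 or 3 or KO L-AC replicates 1, 2 or 3 (adjusted p 0.0527 to 0.161). NRF2 targets, genes of the antioxidant response, were higher by a median of 0.18 (11 of 14 positive, adjusted p = 0.0342), a call lost with age as a covariate (adjusted p = 0.271) and without WT L-AC replicates 1 or 2 or KO L-AC replicate 3 (adjusted p 0.116 to 0.787). Acute phase genes had a median of 0.26 (15 of 19 positive, adjusted p = 0.0422). Their call was lost without WT L-AC replicates 2, 3, 4 or 6 or KO L-AC replicate 1, and without KO L-AC replicate 2 it turned in direction (adjusted p = 0.495). Both lists had an adjusted p of 0.905 with an estimated correlation. No member of the bile acid, NRF2 or acute phase lists passed by the 3 tools or when adjusted over the list alone, and 0, 1 and 2 of them were under 0.05 unadjusted. Cholangiocyte markers were lower by a median of -0.53 (0 of 5 positive, adjusted p = 0.0248, and adjusted p = 0.434 with an estimated correlation), and that call was lost without WT L-AC replicate 5 or KO L-AC replicates 1, 3 or 4 (adjusted p 0.0523 to 0.205). Krt19, a keratin of bile duct cells, was the member that passed when adjusted over the list alone (-2.21, SE 0.645).

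KO and WT livers were also compared with both treatments averaged, a contrast added after the data were seen. It gave 4 genes, of which Ehhadh (-2.86, SE 0.179, adjusted p = 9.91e-10) and Anxa13 (2.18, SE 0.207, adjusted p = 2.26e-06) are those above. Pla1a, a secreted phospholipase specific for phosphatidylserine (chromosome 16, 38396117 to 38433145), was lower in KO (-0.82, SE 0.127, adjusted p = 0.00662). It stood at 18.47 ± 5.57 CPM in WT saline, 10.48 ± 1.603 in KO saline, 14.75 ± 1.896 in WT L-AC and 8.307 ± 1.927 in KO L-AC (SD). Cib3, a calcium-binding protein (chromosome 8, 72204335 to 72212837), was higher in KO (1.73, SE 0.273, adjusted p = 0.00673) at group means from 0.4636 to 2.533 CPM. These 4 were also called by DESeq2 and limma-voom, which gave 24 and 6 genes in all, and the count was 7 without WT saline replicate 1. In this contrast 12 cholesterol synthesis genes passed when adjusted over the list alone (list adjusted p = 1.04e-22, and adjusted p = 0.163 with an estimated correlation). Across the 14196 genes, which are not independent replicates, the genotype effects under saline and under L-AC had a Pearson r of 0.201 and a Spearman rho of 0.087.

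Genes near Ehhadh were tested for an excess of calls, since the alleles around a targeted locus can differ between mutant and WT mice. Within 10 Mb of Ehhadh, 0 of 145 genes other than Ehhadh were called by edgeR in either comparison of KO with WT, against 1 of 14050 elsewhere (two-sided Fisher's exact p = 1 in both). With 1 called gene besides Ehhadh, this test could hardly show an excess. At an unadjusted p under 0.05, a threshold added after the data were seen, 3 of the 145 genes passed under saline (Fisher's exact p = 0.752) and 9 under L-AC (Fisher's exact p = 0.312). Within 5 Mb at that threshold, 2 of 100 genes passed under saline, 2% against 1.85% elsewhere (Fisher's exact p = 0.709). Under L-AC 3 of the 100 did, 3% against 4.53% (Fisher's exact p = 0.63). Within 20 Mb at that threshold, 10 of 283 genes passed under saline, 3.53% against 1.82% elsewhere (Fisher's exact p = 0.0432), and 21 under L-AC, 7.42% against 4.46% (Fisher's exact p = 0.0284). Within 40 Mb, a window also added after the data were seen, 24 of 341 genes passed under saline (7.04% against 1.73%, Fisher's exact p = 2.18e-08) and 29 under L-AC (8.5% against 4.42%, Fisher's exact p = 0.00129). By adjusted p, limma-voom called none of the 145, and DESeq2 called Mb21d2 under L-AC (0.45, SE 0.101, adjusted p = 0.0125), 7.1 Mb from Ehhadh. In the averaged contrast DESeq2 called Mb21d2 (0.32, SE 0.071, adjusted p = 0.00668) and Arvcf (18348182 to 18407074, 0.60, SE 0.14, adjusted p = 0.0238), both within 10 Mb. Farther along chromosome 16 it called Pla1a, Abhd10, Ift57, Crybg3, Timmdc1 and Upk1b in that contrast.

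L-AC changed 7572 of 14196 genes in WT livers (6 against 7 mice), 3781 higher and 3791 lower, of which 887 rose and 1124 fell by more than 2-fold. The largest rises were in Myo16, an unconventional myosin (7.83, SE 1.427), and Tg, the thyroglobulin gene (7.43, SE 0.556, 173-fold). Then came Scn4b, a sodium channel subunit (5.80, SE 0.294), Elovl7, a fatty acid elongase (5.54, SE 0.438), Cxcr1, a chemokine receptor (5.50, SE 0.435), and Pdk4 (5.46, SE 0.373, adjusted p = 1.48e-10). Pdk4, a kinase that inactivates pyruvate dehydrogenase, rose 44-fold. The largest falls were in Ppp1r3c, a glycogen-targeting phosphatase subunit (-5.24, SE 0.482, 37.8-fold), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-5.11, SE 0.579, 34.6-fold). Next were Hsd3b2 (-4.69, SE 0.298), Keg1 (-4.62, SE 0.393), the retinoic acid hydroxylase Cyp26a1 (-4.54, SE 0.449) and the lectin-like receptor Clec2h (-4.49, SE 0.614).

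Of the 37 lists, 13 changed in WT livers by camera with its preset correlation, and 1 of them held with an estimated correlation. That list was lipid droplet and triglyceride genes, in which 12 of 17 rose and 1 fell (median 1.61, adjusted p = 1.61e-10, and adjusted p = 0.012 with an estimated correlation). Its members included the droplet coat protein Plin2 (2.54, SE 0.127), the triglyceride lipase Pnpla2 (2.67, SE 0.156) and Hilpda, an inhibitor of that lipase (4.44, SE 0.34). Of the targets of PPARA, the fatty acid receptor that controls hepatic lipid catabolism, set apart from the oxidation genes, 14 of 17 rose (median 1.16, adjusted p = 1.51e-10, and adjusted p = 0.0639 with an estimated correlation). They included Slc22a5, the carnitine importer (2.06, SE 0.126), and Cpt1b, a carnitine palmitoyltransferase (2.36, SE 0.19). In peroxisomal beta-oxidation without Ehhadh, 15 of 27 rose and 4 fell (median 0.51, adjusted p = 0.000823, and adjusted p = 0.183 with an estimated correlation). Its members included the carnitine acetyltransferase Crat (1.68, SE 0.15) and the transporter Abcd3 (1.19, SE 0.104). Peroxisome biogenesis had 9 of 16 higher and 3 lower, or 10 and 4 adjusted over the list alone (median 0.34, adjusted p = 0.00296, and adjusted p = 0.183 with an estimated correlation), with Pex11a, a factor of peroxisome division, at 2.08 (SE 0.218) and Pex19, an import receptor for peroxisomal membrane proteins, at 1.01 (SE 0.065). In mitochondrial fatty acid oxidation 10 of 18 rose and 3 fell (median 0.43, adjusted p = 0.00763, and adjusted p = 0.904 with an estimated correlation), with Cpt2 at 0.75 (SE 0.079) and the acyl-CoA dehydrogenase Acadl at 0.87 (SE 0.075).

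Among the lists that fell in WT livers, 16 of 20 cholesterol synthesis genes were lower and 1 higher (median -1.61, adjusted p = 3.11e-06, and adjusted p = 0.426 with an estimated correlation). Idi1, an isoprenoid isomerase, fell by 3.15 (SE 0.426), and the changes of Msmo1 and the thiolase Acat2 were -2.75 (SE 0.382) and -2.07 (SE 0.147) on the log2 scale. In sterol uptake and SREBP2 feedback 6 of 7 were lower (median -1.54, adjusted p = 3.11e-06, and adjusted p = 0.183 with an estimated correlation), among them Insig1 (-2.61, SE 0.182). In bile acid synthesis 7 of 10 were lower and 2 higher (8 and 2 adjusted over the list alone, median -0.64, adjusted p = 0.00366, and adjusted p = 0.0944 with an estimated correlation), with Akr1d1, a steroid reductase of the pathway, at -2.29 (SE 0.326). In bile acid transport and FXR signalling 9 of 13 were lower and 1 higher, or 9 and 2 adjusted over the list alone (median -0.84, adjusted p = 0.000823, and adjusted p = 0.183 with an estimated correlation). The canalicular bile salt pump Abcb11 was at -2.44 (SE 0.247), the bile acid importer Slc10a1 at -1.51 (SE 0.111) and Nr0b2, a repressor induced by FXR, at -4.00 (SE 0.539).

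All 17 interferon response genes fell (median -1.26, adjusted p = 3.11e-06, and adjusted p = 0.323 with an estimated correlation), with Isg15, a ubiquitin-like protein, at -2.20 (SE 0.325) and the GTPase Irgm1 at -1.38 (SE 0.147). Of 11 genes of pericentral hepatocytes, those around the central vein, 8 fell, or 9 adjusted over the list alone (median -0.94, adjusted p = 0.00418, and adjusted p = 0.272 with an estimated correlation). They included the Wnt co-receptor Lgr5 (-2.60, SE 0.344) and glutamine synthetase Glul (-1.04, SE 0.211). Of 16 male-biased liver genes 10 fell and 1 rose, or 11 and 1 adjusted over the list alone (median -0.78, adjusted p = 0.00763, and adjusted p = 0.426 with an estimated correlation), with the steroid dehydrogenase Hsd3b5 at -4.48 (SE 0.538). Of 14 ER chaperone genes 5 fell (median -0.64, adjusted p = 0.0365, and adjusted p = 0.942 with an estimated correlation). That call was lost without WT saline replicates 1 or 6 or WT L-AC replicates 1, 2 or 3 (adjusted p 0.0632 to 0.0955). Where a list has a single set of counts here, the counts adjusted over the list alone were the same. Hsd3b2 and Hsd3b5 belong to a family of similar genes, like the Cyp4a, Cyp2b, Acot and Orm genes. A read that matched several members was counted at its primary alignment alone, so the share of each member is uncertain, and the number of such reads was not measured.

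**Figure D3:**
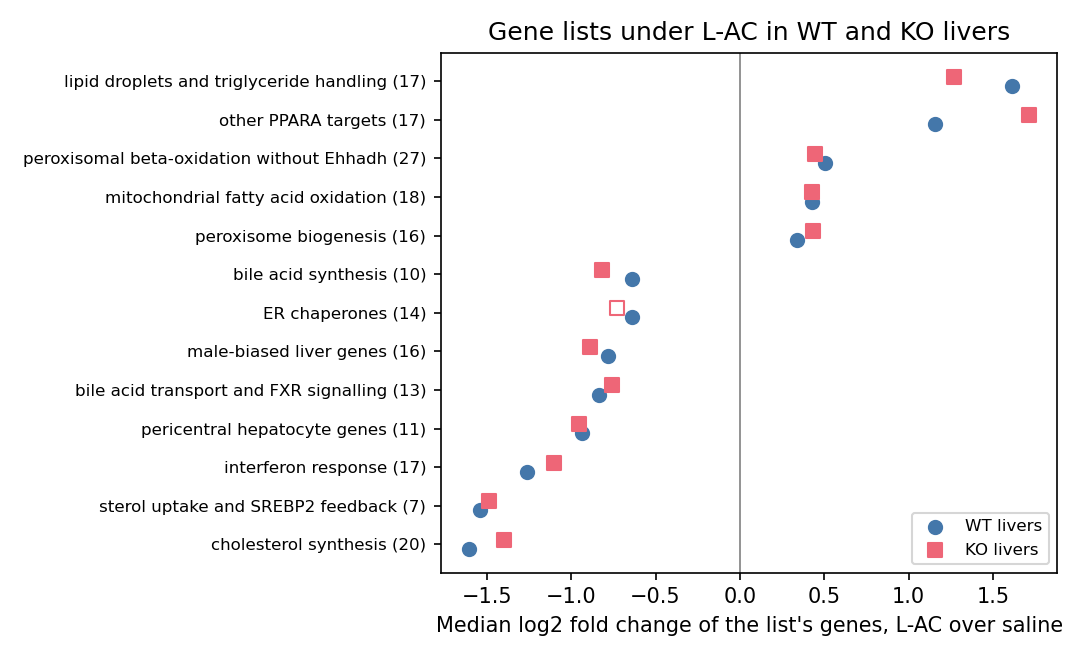
Median log2 fold change of L-AC against saline in WT (blue) and KO (red) livers for the gene lists that passed camera in either genotype, with the number of genes tested in parentheses. Filled points passed camera with its preset correlation and the open point, ER chaperones in KO, did not (-0.73, adjusted p = 0.123).

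In several lists whose camera test did not pass, members moved in both directions in WT livers. Glucose handling was one such list: of 12 genes of glycolysis and glucose uptake 6 rose and 6 fell (adjusted p = 0.715), with the glucose transporter Slc2a2 at -2.51 (SE 0.352), against Pgk1 at 0.48 (SE 0.072). In fatty acid synthesis 4 of 17 rose and 6 fell (adjusted p = 0.715). Acacb, whose product malonyl-CoA inhibits carnitine palmitoyltransferase 1, was at 2.85 (SE 0.228) and Mlxipl, a transcription factor of lipogenic genes, at -1.66 (SE 0.138). In gluconeogenesis and fasting 5 of 11 rose and 3 fell, with a median of -0.11, a mean of 0.32 and an adjusted p of 0.86. No list of markers of another cell type passed, the smallest adjusted p being 0.451, for erythroid markers, of which 1 of 5 was lower (Alas2, -0.77, SE 0.127).

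In KO livers (5 against 5 mice) L-AC changed 6924 genes, 3571 higher and 3353 lower, with 977 raised and 1178 lowered by more than 2-fold. After Myo16 (7.85, SE 1.667) and Tg (7.40, SE 0.65), the largest rises were in Bmper, a regulator of bone morphogenetic protein signalling (6.15, SE 0.567), Elovl7 (6.05, SE 0.522), the fatty acid-binding protein Fabp3 (5.74, SE 1.137) and Cxcr1 (5.74, SE 0.534). The largest falls included Cyp7a1 (-6.10, SE 0.687, 68.7-fold), Hsd3b2 (-4.98, SE 0.341), AW549542 (-4.90, SE 0.45), Ppp1r3c (-4.69, SE 0.523) and Clec2h (-4.44, SE 0.665). Myo16 was near the floor without L-AC, at 0.0168 CPM in WT saline livers, so its fold in both genotypes depends on the fit.

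In KO livers 12 lists changed by camera, and 2 of them held with an estimated correlation. Lipid droplet genes rose in 13 of 17 members and fell in 1 (median 1.27, adjusted p = 2.94e-09, and adjusted p = 0.0153 with an estimated correlation), with Cidec, a protein of droplet growth, at 5.34 (SE 0.478). Bile acid synthesis genes fell in 8 of 10 (median -0.82, adjusted p = 0.000202, and adjusted p = 0.0196 with an estimated correlation). The other PPARA targets rose in 13 of 17 (median 1.72, adjusted p = 1.5e-09, and adjusted p = 0.07 with an estimated correlation), with Pdk4 at 5.57 (SE 0.44) and the thioesterase Acot2 at 3.67 (SE 0.339). Peroxisomal beta-oxidation without Ehhadh had 16 of 27 higher and 5 lower (median 0.44, adjusted p = 0.0038, and adjusted p = 0.289 with an estimated correlation), with Crat at 1.48 (SE 0.172). Peroxisome biogenesis had 9 of 16 higher and 2 lower (median 0.44, adjusted p = 0.00323, and adjusted p = 0.243 with an estimated correlation). In mitochondrial fatty acid oxidation 10 of 18 were higher and 3 lower (median 0.43, adjusted p = 0.0122, and adjusted p = 0.855 with an estimated correlation), a call lost without KO L-AC replicate 4 (adjusted p = 0.0519).

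Cholesterol synthesis genes fell in 16 of 20 members in KO livers and rose in 1 (median -1.40, adjusted p = 2.37e-05, and adjusted p = 0.515 with an estimated correlation), with Acat2 at -1.94 (SE 0.164). Sterol uptake genes fell in 6 of 7 (median -1.49, adjusted p = 0.000152, and adjusted p = 0.289 with an estimated correlation). Bile acid transport fell in 9 of 13 and rose in 1 (median -0.76, adjusted p = 0.000265, and adjusted p = 0.243 with an estimated correlation), with Abcb11 at -2.67 (SE 0.278). Interferon response genes fell in 11 of 17, or 13 adjusted over the list alone (median -1.10, adjusted p = 0.000157, and adjusted p = 0.515 with an estimated correlation). Pericentral genes fell in 7 of 11, or 8 adjusted over the list alone (median -0.96, adjusted p = 0.00335, and adjusted p = 0.289 with an estimated correlation). Male-biased genes fell in 8 of 16 and rose in 1 (median -0.89, adjusted p = 0.0133, and adjusted p = 0.515 with an estimated correlation). Counts for the KO lists not given a second value were the same adjusted over the list alone.

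Across the 14196 genes, which are not independent replicates, the log2 fold changes of L-AC in WT and in KO livers had a Pearson r of 0.935 and a Spearman rho of 0.918, with a slope of 0.994 for KO on WT. Genes higher in both numbered 3087, against 951.11 if the calls were independent, and genes lower in both numbered 2918, against 895.41. No gene was called in opposite directions, and the 2 comparisons share no library. The interaction, the difference between the responses, gave 0 genes by edgeR, 0 by DESeq2 and 0 by limma-voom. At an unadjusted p under 0.05 they gave 320, 421 and 310. The simulations did not cover the interaction, so the size of difference it could detect was not measured. The absence of calls does not show that the responses are equal. Of the 37 lists, 4 passed camera for the interaction (bile acid synthesis, ATF4 targets, acute phase and endothelial markers), each lost without at least 1 library and with an estimated correlation (adjusted p 0.236 for bile acid synthesis and 0.983 for the others).

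**Figure D4:**
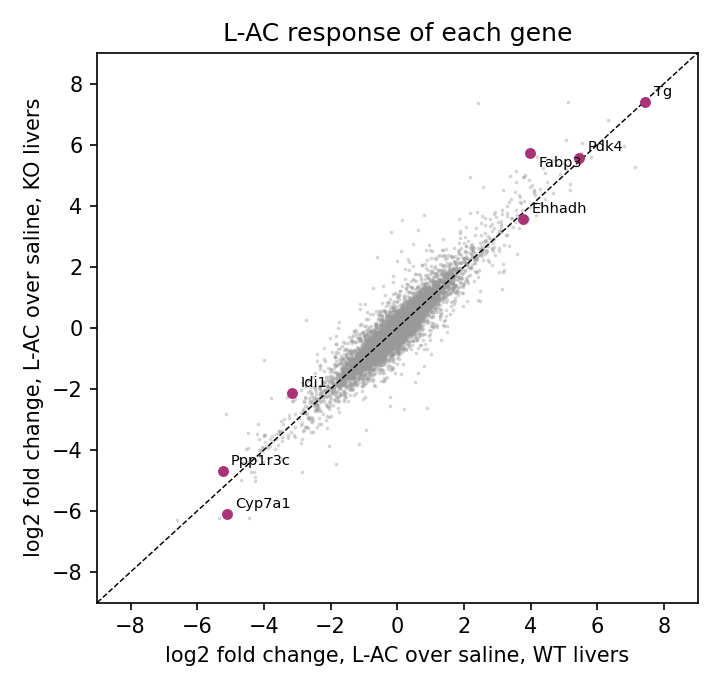
Log2 fold change of L-AC against saline in WT livers (x axis) and in KO livers (y axis), a point for each of the 14196 genes tested, with named genes labelled and a dashed line where both changes are equal. The regression of KO on WT has a slope of 0.994 and a Pearson r of 0.935.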

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

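The tests of Ehhadh reads in KO libraries were chosen after the result was seen. In 168 tests of a group's highest or lowest library against the rest, 11 stood apart, where chance gives about 1 in 20, or 8.4. In liver of KO mice on saline, Ehhadh was at 252.9 CPM in replicate 3, with the nearest library at 131.6. The mean log2 CPM of gluconeogenesis and fasting genes was 8.77 in WT saline replicate 1 (nearest 8.168) and 8.39 in KO saline replicate 2 (nearest 7.971). ATF4 targets stood at 3.778 in WT saline replicate 1 (nearest 3.027). Circadian clock genes stood at 4.933 in WT saline replicate 4 (nearest 4.417), and cell cycle genes at 0.663 in KO saline replicate 4 (nearest 0.416). KO saline replicate 1 was lowest for fatty acid synthesis (5.897, nearest 6.322) and for stellate cell and fibroblast markers (2.212, nearest 3.087). Macrophage markers were at 2.464 in KO saline replicate 2 (nearest 1.809). Pancreatic acinar markers were at 3.538 in KO saline replicate 5 (nearest 2.352) and at 2.59 in WT L-AC replicate 5 (nearest 1.627).

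In 4 lists the response to L-AC differed between genotypes by camera's test of the interaction. No member of the 4 was called by edgeR, DESeq2 or limma-voom, and 1, 2, 3 and 1 members were under 0.05 unadjusted in the order below. The response of bile acid synthesis genes was lower in KO by a mean of -0.30 on the log2 scale (adjusted p = 0.00951), a call lost without WT saline replicate 7 or KO L-AC replicates 2 or 3 (adjusted p 0.0537 to 0.0707). That of ATF4 targets was higher in KO by 0.79 (adjusted p = 0.000276), lost without KO L-AC replicate 3 (adjusted p = 0.061). That of acute phase genes was higher by 0.90 (adjusted p = 0.000276), lost without KO L-AC replicate 2 (adjusted p = 0.405). That of endothelial markers was lower by a mean of -0.14 (adjusted p = 0.0299). This last call was lost with age as a covariate (adjusted p = 0.234) and without WT saline replicates 1, 2, 3 or 5, KO saline replicates 2 or 3, WT L-AC replicates 1 or 5, or KO L-AC replicates 2, 3 or 5 (adjusted p 0.0555 to 0.324). With an estimated correlation the adjusted p was 0.236 for bile acid synthesis and 0.983 for the other 3. Of 100 splits of the genotypes within each treatment, the real one included, 87 gave at least as many lists as the real 4 (highest other 16), and 87 gave at least as many genes as the real 320 at an unadjusted p under 0.05 (highest other 2068). Chance is therefore not excluded for either count. Splits with several times the real number may reflect a structure of the samples other than genotype, which was not tested.

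Ehhadh reads in KO libraries rose with L-AC as they did in WT. A fixed share of reads carried over from all libraries is argued against by the 11.7-fold rise in KO livers, since such a share would stay about the same across the treatments. RNA from WT livers of the same treatment would keep the KO level at a constant percentage of WT. The percentage was 14.8 ± 6.74 under saline and 12.7 ± 2.2 under L-AC (SD, n = 5 and 5, exact permutation p = 0.706), which does not separate this source from transcripts of the targeted allele that may still be made and counted over its remaining exons. The 2 cannot be told apart here, because both predict the same percentage and the counts are summed over the gene.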

How the results depend on the processing

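The averaged contrast was chosen after the data were seen. With DESeq2, which tested 19815 genes, the calls were 9 for KO against WT under saline, 16 under L-AC and 24 for the averaged contrast, against 2, 2 and 4. A fit of only the groups compared gave 5 genes under L-AC, among them Ehhadh, Igfbp5 (-1.66), Fdps (1.02) and Msmo1 (1.04). The cause was not tested. Leaving out each library gave 2 to 5, 2 to 6 and 4 to 7 genes. Lists called with an estimated correlation numbered 0 under saline, 0 under L-AC, 1 for L-AC in WT, 2 for L-AC in KO and 0 for the interaction, which follows from the larger correlation used. Leaving out each library gave 1 to 7 lists under saline, 4 to 9 under L-AC and 1 to 5 for the interaction. The acute phase list under L-AC turned in direction without KO L-AC replicate 2 (adjusted p = 0.495, range over the libraries left out 1.91e-05 to 0.495), and the cause was not tested. The counts for L-AC stayed within 1.5 times, from 5670 at an adjusted p under 0.01 to 7900 with DESeq2 in WT and from 5006 to 7198 in KO. Ehhadh kept its call, at -3.07 to -2.57 under saline and -3.08 to -2.92 under L-AC with each library left out. The correlation of genotype effects ranged from 0.152 to 0.253 and that of L-AC effects from 0.912 to 0.938, and no gene was called for the interaction with any library left out. A sex covariate was not run because all libraries have Y-linked reads, and the correlation over called genes alone could not be given for genotype, with 2 genes. At the depth and group sizes of the genotype comparisons, 1.5-fold changes were recovered in 40% and 44% of simulated genes and 4-fold changes in 96% and 98%, and no simulation varied depth or group size. Simulated genes were drawn independently, so recovery among real, correlated genes may differ. It may also be lower in the genotype comparisons, where few genes were called, since the adjustment of p is then stricter than in the simulation.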

Other observations

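The tests of age, a single library and linked alleles, the averaged contrast, the score permutations and the counts over chromosome 16 were chosen after the results were seen. Several lists not described above held members that moved apart under L-AC. Among ATF4 targets 7 of 18 rose and 3 fell in WT (median 0.24, camera adjusted p = 0.672) and 9 rose and 2 fell in KO (median 1.19, adjusted p = 0.0621). Psat1, an enzyme of serine synthesis, rose by 1.87 (SE 0.515) in WT and 3.10 (SE 0.62) in KO on the log2 scale, and Mthfd2, of mitochondrial one-carbon metabolism, by 2.24 (SE 0.476) in KO. NRF2 targets went both ways in WT livers, 6 of 14 up and 5 down (adjusted p = 0.881), with the peroxiredoxin reductase Srxn1 at 2.07 (SE 0.225), and Gclc, of glutathione synthesis, at -1.56 (SE 0.268). CAR and PXR targets had 3 of 12 up and 1 down in WT (median -0.21, mean 0.22, adjusted p = 0.891), with Cyp2b10, a drug-metabolising P450, at 3.97 (SE 0.579) and the P450 reductase Por at 1.77 (SE 0.236). Of 14 lipoprotein genes 2 rose and 5 fell in WT (adjusted p = 0.715), with Apoa4 at 3.73 (SE 0.423), Mttp, which loads lipid onto apolipoprotein B, at 1.02 (SE 0.09) and the hepatic lipase Lipc at -1.11 (SE 0.116). Of 10 LXR targets 3 rose and 4 fell (median 0.14, mean -0.14, adjusted p = 0.881), with the phospholipid-remodelling Lpcat3 at 0.85 (SE 0.085) and the sterol exporter subunit Abcg5 at -1.39 (SE 0.174).

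Markers of immune cells and of the cell cycle also moved apart under L-AC in WT livers. Of 12 macrophage markers 2 rose and 5 fell (adjusted p = 0.715), Gpnmb, a marker of lipid-laden macrophages, by 4.09 (SE 0.619) and Cd68, a lysosomal glycoprotein, 2.83-fold (log2 SE 0.403), against Lyz2, lysozyme, at -0.94 (SE 0.28) and Cd5l at -1.03 (SE 0.34). Of 5 lymphocyte markers 1 rose and 4 fell (adjusted p = 0.715), the T cell gene Cd3e at 1.49 (SE 0.273) and the B cell gene Ms4a1 at -1.64 (SE 0.445), both at levels under 1 CPM. Among 12 cell cycle genes 3 rose and 2 fell (adjusted p = 0.902), with Mcm2, of DNA replication licensing, at 1.48 (SE 0.18), and the mitotic genes Birc5 at -2.72 (SE 0.325) and Ccnb2 at -1.73 (SE 0.362). Of 14 circadian clock genes 1 rose and 5 fell (adjusted p = 0.715), with Hlf at -0.81 (SE 0.168) and Per1 at 0.99 (SE 0.248). Of 10 periportal genes 3 rose and 5 fell (adjusted p = 0.516), the urea cycle enzyme Arg1 by 1.19 (SE 0.17) and Cyp2f2 at -1.62 (SE 0.167).

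Splits of the libraries of the 2 groups compared, 100 for each comparison with the real one included, were fitted like the real data. For L-AC against saline no other split gave as many genes, in WT (1 of 100, real 7572, highest other 5947) or in KO (1 of 100, real 6924, highest other 1982), so chance is excluded for these counts. For the count of genes between KO and WT chance is not excluded under saline (5 of 100 gave at least the real 2 genes, highest other 46) or under L-AC (8 of 100, real 2, highest other 2067). For the averaged contrast 3 of 100 gave at least the real 4 (highest other 290). That contrast was chosen after the data were seen and its 4 genes include the targeted Ehhadh, so chance is not taken as excluded there either. This concerns the counts and not the 2 genes called, Ehhadh and Anxa13, each of which separated every KO from every WT library of the same treatment under saline and again, in other mice, under L-AC (Anxa13 at adjusted p = 0.00073 and 0.00159). Counts of lists called do not exclude chance: 90 of 100 splits gave at least the real 4 under saline (highest other 16), 45 the real 7 under L-AC (highest other 16), 15 the real 13 for L-AC in WT (highest other 18) and 25 the real 12 for L-AC in KO (highest other 17). Lists were also tested one at a time, by an exact permutation of the mean log2 CPM adjusted over the 37 lists. By it 19 lists differed between L-AC and saline in WT and 19 in KO (adjusted p under 0.05). Between KO and WT 0 did under either treatment (1 under saline and 2 under L-AC at an unadjusted exact p under 0.05, and 4 and 7 by camera). This permutation asks whether a list changed at all, whereas camera asks whether it changed more than other genes. Of all genes tested, 53.3% were called for L-AC in WT and 48.8% in KO. Many lists of any kind would therefore differ, and the 19 in each genotype do not single out pathways. What the splits that called many times the real number of genes have in common was not tested, and a structure of the samples other than genotype may underlie them.

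A first hypothesis is that loss of Ehhadh leaves cholesterol synthesis genes higher in liver, most evenly under L-AC. It did not come from these data alone, since the list was written knowing that the title of the series names cholesterol homeostasis. For the list's camera p with the preset correlation, the real split ranked 1 of 100 under L-AC (real 5.13e-14, smallest other 7.15e-08) and averaged (real 2.82e-24, smallest other 1.92e-22). Under saline it ranked 12 of 100 (real 2.33e-14, smallest other 6.93e-50). A rank of 1 of 100 for 1 of 37 lists does not exclude chance. The averaged mean log2 fold change of the list was 0.485, and other splits reached 0.473 and -0.482. None of these calls held with an estimated correlation (adjusted p = 0.434, 0.163 and 0.77 in that order), and the exact permutation of the score gave an adjusted p of 0.0801 over the 37 lists under L-AC, and p = 0.00767 with both treatments together over 365904 arrangements (mean difference 0.503 on the log2 scale). Age as the whole cause is argued against by the mean log2 fold change of the list under L-AC, 0.564 and 0.531 with age in the fit. The SE of 0.1 for the first value is over the members, which come from the same mice. It does not measure the spread between animals. A single library as the cause is argued against by the lowest mean with each library left out, 0.524. Litter or day of collection, which the labels do not give, may still separate the groups and stays untested, as does a difference in feeding.

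A second hypothesis is that mutant mice carry other alleles on chromosome 16 linked to the targeted locus. At an unadjusted p under 0.05 in the averaged contrast, 40 of 442 genes of the chromosome passed (9.05% against 3.61% elsewhere, Fisher's exact p = 3.24e-07). Adjusted over 20 chromosomes, that Fisher's exact p was 6.48e-06, and chromosome 17 had an adjusted p of 0.0258. Within 40 Mb of Ehhadh 39 of 341 genes passed (11.44% against 3.59%, Fisher's exact p = 6.66e-10). Within 20 Mb 19 of 283 did (6.71% against 3.72%, Fisher's exact p = 0.0166), and within 10 Mb 6 of 145 (4.14% against 3.78%, Fisher's exact p = 0.825). These windows are nested, so the hits were densest between 20 and 40 Mb from Ehhadh and not next to it. For the excess of the chromosome in percentage points, the real split ranked 1 of 100 under saline (real 4.159, highest other 2.805). Averaged it also ranked 1 of 100 (real 5.436, highest other 3.206). Under L-AC it ranked 2 of 100 (real 3.038, highest other 4.733), and 4 other splits gave 2.942 to 3.034. The counts over this chromosome were chosen after the data were seen, so chance is not taken as excluded for its excess. A few libraries as the source are argued against by the largest Fisher's exact p with each library left out, 0.000463 for the averaged contrast, although under L-AC alone it reached 0.166 without KO L-AC replicate 4 and was over 0.05 for 6 of 23 libraries. Across the 283 genes within 20 Mb the effects under saline and L-AC had a Pearson r of 0.524, against 0.182 on other chromosomes. Their signs were the same in 161 of the 283 (56.9%), against 51.4% on other chromosomes. Such an r would follow from linked alleles or from an effect of the loss of Ehhadh. The excess on chromosome 16 goes with linked alleles, since loss of Ehhadh would by itself give no reason for hits to gather there. Against this, no excess was seen at an unadjusted p under 0.05 within 10 Mb or 5 Mb, where linkage is closest. Within 5 Mb the share in the averaged contrast was 3% against 3.79% elsewhere. No genotype of the flanking region was used here, so the question stays open.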
